A study of Mus musculus with 6 samples.

How the data were processed

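Left ventricular tissue of male C57BL/6 mice from 2 groups was measured, with 3 libraries per group: ET (5% ethanol diet for 10 days and 1 ethanol gavage) and CONT (isocaloric diet and maltose-dextrin gavage). Per the labels' protocols, hearts were taken 9 h after the gavage, 1000 ng of total RNA went into a NuGEN Universal mRNA Plus library, and about 15 M paired reads of 75 bp per library were planned on a NextSeq550. The deposited totals, from 28838386 to 37762233 expected counts per library, lie above that number. Replicate numbers follow the order of deposit and pair nothing.

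Reads were aligned with STAR 2.7.0f and quantified with RSEM 1.2.31 on the mm10 build, per the submitters' processing notes. The annotation release and the use of strand are not given in the sources used here, so a gene and an overlapping gene on the opposite strand cannot be told apart. The authors deposited a table of expected counts, estimated counts per gene that were not normalized and need not be whole. Of the nonzero values 65.7% to 67.3% were whole within 0.005. TPM values were deposited in 1 file per library, scaled by the authors to a fixed sum over the genes, and FPKM values stand beside them, per the file headers. Expected counts were rounded to whole numbers for all count tests, TPM entered 2 alternatives, and the effective gene length was taken as the ratio of expected counts to FPKM, scaled by the library total. The files list 55487 Ensembl gene IDs with symbols, of which 29737 had a count in any library. In the GENCODE vM21 annotation (GRCm38) 55394 of them were found, 54586 with the same symbol, and 110 symbols belonged to more than 1 ID. Coordinates and exon overlaps come from that annotation.

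The libraries of each group differed from each other by far more than sampling noise (chi-square per gene from 18.8 to 190 between libraries of a group). This cannot tell separate mice from technical spread, and each library was counted as 1 sample. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 15727. TMM factors were 0.968, 0.927 and 1.004 in CONT replicates 1 to 3 and 1.19, 1.01 and 0.920 in ET replicates 1 to 3, and CPM values were scaled with them. ET was compared with CONT by edgeR's robust quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, with no covariate. The common biological coefficient of variation was 0.297. The SE of a log2 fold change was its size divided by the square root of the F statistic. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.

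The groups, tests, alternatives, the 42 gene lists and the rule for named genes were fixed before the data were examined. Under that rule the text names, among genes with an adjusted p under 0.05, a mean CPM of at least 1, no overlap between groups and a name that is neither a predicted locus nor a pseudogene, those of the largest change in each direction. If fewer than 5 genes pass, it names the 10 with the lowest p under the same CPM and name conditions and says that they did not pass, which is the case here; 1 of the 10 genes, and 1 test of ET replicate 3, are not reported here. Of a described list it names at most 2 members by lowest p where none passes over all genes. Lists cover metabolism, stress responses, contraction, inflammation, the cell cycle and markers of 14 cell or tissue types. Each list of at least 5 tested genes (41 of 42) was tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry.

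The tests were tried on simulated counts with the means and library sizes of these 15727 genes and 100 genes changed at each fold. For a 2-fold change edgeR called 16 of 100, DESeq2 44 and limma-voom 10, and for a 4-fold change 82, 97 and 81. False calls numbered 13, 55 and 8, and with no changed gene edgeR called 0, DESeq2 28 and limma-voom 0. In 10 simulations without change, 0 to 1 of 41 lists were called, and a list shifted by 0.5 (log2) was called, along with 3 others. Genes were simulated independently of each other, whereas the correlation estimated within the lists of the data had a median of 0.397 and reached 0.912. These simulations therefore cannot show how often camera calls lists of correlated genes by chance.

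Alternatives were RLE and upper-quartile factors, library totals only, no filter and a stricter one (CPM of at least 1 in 3 libraries), DESeq2, limma-voom, limma-trend on log2(TPM + 1) and log2(TPM + 0.1) for genes with a mean TPM of at least 0.5, and removal of mitochondrially encoded genes or the 10 most abundant genes. A test against a fold of 1.2, a threshold of 0.10, and leaving out each library in turn complete them. Fits with a term for the library sets, fits without CONT replicate 3 and ET replicate 1, and DESeq2 without each library were added after seeing the data. Library sets were read from genes with counts over 200 and FPKM over 1 in each library. Ratios within sets are log2 ratios of mean CPM, with 0.5 added for the list medians and nothing added for the named genes. Expected counts of the per-library files were planned as an alternative and are not used here, since those files gave TPM and FPKM.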

Results

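The left ventricle, the main pumping chamber of the heart, was profiled by bulk RNA sequencing in 8-week-old male C57BL/6 mice in a study of alcoholic cardiomyopathy, a heart muscle disease of heavy drinking. Mice of the ET group received a diet with 5% ethanol for 10 days and then a single ethanol gavage, and mice of the CONT group received an isocaloric diet and a maltose-dextrin gavage. Tissue was taken 9 h after the gavage. There were 6 libraries, 3 per group, and the labels do not say that each came from a separate mouse, so p-values measure only the spread between these samples, which may be technical. The libraries held 37762233, 28838386 and 33696699 expected counts in CONT replicates 1 to 3 and 31553420, 33599269 and 33425756 in ET replicates 1 to 3. Mitochondrially encoded genes took 27.8% to 31.9% of the counts, and the 10 most abundant genes of a library took 34.5% to 39.9%. Of 55487 genes in the files, 15727 had enough counts to be tested.

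The comparison of ET with CONT asks which ventricular transcripts differ after short ethanol feeding and a binge. The ET libraries had more mRNA of Angptl4, a secreted inhibitor of lipoprotein lipase (28.2 ± 8.02 CPM against 9.66 ± 0.646, SD, n = 3 per group), of Aldh1a1, a cytosolic aldehyde and retinal dehydrogenase (35.8 ± 7.65 against 15.8 ± 0.138), and of Mylip, a ubiquitin ligase for the low-density lipoprotein receptor (52.2 ± 4.54 against 27.9 ± 1.70). They had less mRNA of Dbh, the enzyme that makes noradrenaline (0.718 ± 0.164 against 2.48 ± 0.199), and of Rnf207, a RING finger protein linked to cardiac repolarisation (35.9 ± 5.09 against 78.4 ± 11.2). No single gene passed the test across all genes. Among gene lists fixed before the data were examined, glucocorticoid-responsive genes (median log2 fold change 0.73) and FoxO targets (0.47) moved up as groups in the camera test, and nuclear-encoded respiratory chain genes (-0.38, lowest on average in ET replicate 1) moved down, and none of these calls held with an estimated correlation between genes.

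The 10 genes named by the rule, those with the lowest p, did not pass: each had an adjusted p of 0.427 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In all 10 the CPM ranges of the groups did not overlap, with 6 higher in ET in all 3 of its libraries and 4 lower. Values are given for 9 of them, 5 higher and 4 lower. The log2 fold changes (ET over CONT, ± SE) of the higher ones were 1.54 ± 0.21 for Angptl4, 1.25 ± 0.19 for Il6ra, a subunit of the interleukin-6 receptor, and 1.18 ± 0.18 for Aldh1a1. Trp53inp1, a p53-induced stress protein, had 1.001 ± 0.14 (18.3 ± 0.522 against 9.13 ± 1.29), and Mylip had 0.90 ± 0.13. The values of the lower ones were -1.78 ± 0.29 for Dbh, -1.14 ± 0.19 for Ybx2, a Y-box nucleic acid-binding protein (8.97 ± 1.06 CPM against 19.8 ± 4.15), -1.12 ± 0.17 for Rnf207 and -0.91 ± 0.13 for Ppm1j, a protein phosphatase (8.61 ± 0.521 against 16.2 ± 1.504). Il6ra was at 8.99 ± 0.771 CPM against 3.78 ± 0.718. Aldh1a1 has a close paralog, Aldh1a7, at a mean of 1.28 CPM in ET and 0.327 in CONT, so a share of its reads is uncertain, and part of Il6ra (2.80% of its exon bases) and of Rnf207 (1.63%) overlaps a gene on the opposite strand.

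On the GRCm38 (mm10) build, these 9 protein-coding genes lie at the following places, and each value covers all exons of the gene. Angptl4 (ENSMUSG00000002289) is on chromosome 17 at 33773750 to 33781830 (minus strand) and Trp53inp1 (ENSMUSG00000028211) on chromosome 4 at 11156431 to 11174379 (plus). Ppm1j (ENSMUSG00000002228) is on chromosome 3 at 104781056 to 104786018 (plus), Mylip (ENSMUSG00000038175) on chromosome 13 at 45389742 to 45412022 (plus) and Aldh1a1 (ENSMUSG00000053279) on chromosome 19 at 20492715 to 20643465 (plus). Rnf207 (ENSMUSG00000058498) is on chromosome 4 at 152307019 to 152318993 (minus) and Il6ra (ENSMUSG00000027947) on chromosome 3 at 89864059 to 89913196 (minus). Dbh (ENSMUSG00000000889) is on chromosome 2 at 27165233 to 27183200 (plus) and Ybx2 (ENSMUSG00000018554) on chromosome 11 at 69935796 to 69941605 (plus).

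**Figure D1:**
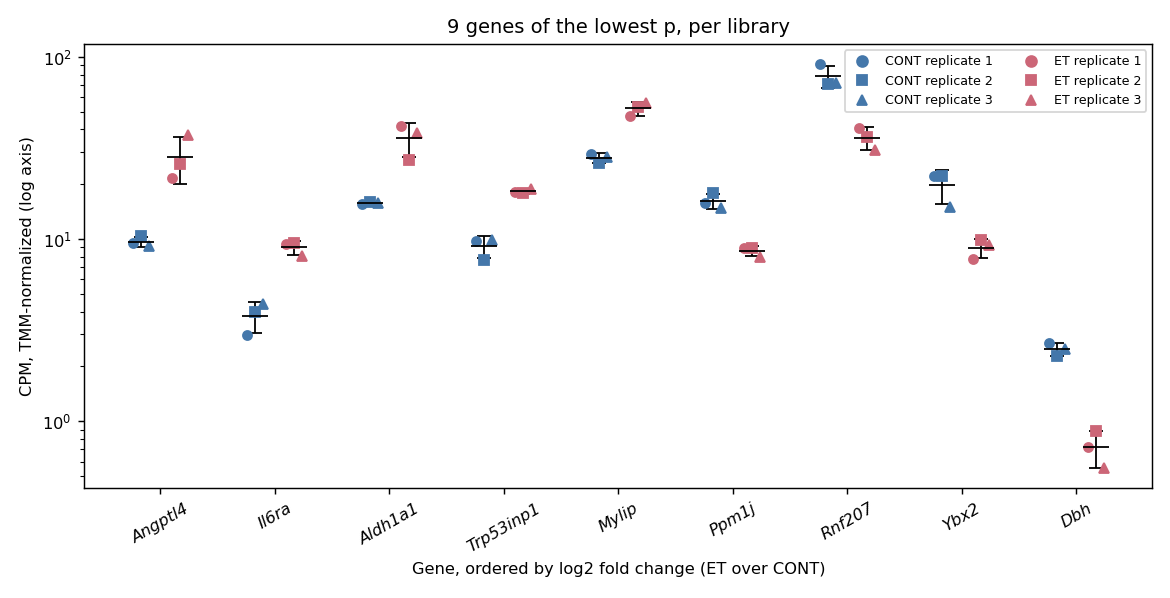
TMM-normalized CPM (log axis) of the 9 genes in each of the 3 CONT and 3 ET libraries; colour gives the group and marker shape the replicate, and the horizontal bar with whiskers gives the group mean ± SD. In each gene the values of the groups do not overlap, from Angptl4 at 1.54 to Dbh at -1.78 in log2 fold change.

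In edgeR, 0 of 15727 genes passed an adjusted p of 0.05, the lowest being 0.427, and 1360 had an unadjusted p under 0.05 (659 higher and 701 lower in ET). DESeq2 on the same counts called 184 genes (105 higher, 79 lower), and 28 in simulated data with no change. Without single libraries its count was 21 and 38 (CONT replicates 1 and 2), 437 (CONT replicate 3) and 405 (ET replicate 1). Limma-voom called 0 with 1277 at an unadjusted p under 0.05, and the 10 named genes had DESeq2 adjusted p from 4.28e-06 to 0.00104, within a range of 4.28e-06 to 0.999 over all alternatives. The CPM values of the groups did not overlap in 2398 genes (15.2%, against 10% by chance), of which 1084 were higher in ET. Other splits of the 6 libraries into 3 and 3 gave from 3.73% to 29.4%, so the excess over 10% is not read as an effect of the group. With CONT replicate 3 and ET replicate 1, the libraries of the highest atrial markers, left out together, edgeR called 828 genes (529 higher, 299 lower), and the remaining CONT and ET libraries then also belonged to different library sets, so that group and set could not be told apart. The first principal components, with 37.4% and 30.7% of the variance, did not separate the groups: ET replicates 1 and 3 lay at the opposite ends of the first (-61.9 and 58.8).

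The libraries also fell into sets that cross the groups. The effective gene lengths in the files placed CONT replicates 1 and 2 with ET replicate 1 (set 1) and CONT replicate 3 with ET replicates 2 and 3 (set 2). Of 8077 well-covered genes, 1995 (24.7%) had effective lengths that did not overlap between the sets, against 1017 (12.6%) between ET and CONT. The sets were chosen as the split, of the 10 into 3 and 3, with the most such genes, so that they rank first by construction. A log2 gap over 0.3 was found in 44 genes between the sets and in 2 between ET and CONT, so the wide gap of Myh6 is not typical. For Myh6, the main adult myosin heavy chain, the effective length was 1309, 1365 and 1347 bases in set 1 and 2061, 2157 and 2370 in set 2. In sets 1 and 2 the log2 ratio of ET to CONT was 1.12 and 1.79 for Angptl4, -1.51 and -0.65 for Ybx2 and -1.79 and -1.79 for Dbh. Each of these ratios rests on 1 ET library in set 1 or 1 CONT library in set 2. With a term for the set in the edgeR fit, 0 genes passed, 1579 had an unadjusted p under 0.05, and the 10 named genes, chosen for the lowest p, had log2 fold changes of 0.86 to 1.78 in size and did not pass (adjusted p 0.360 each).

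Camera with a preset correlation of 0.01 called 24 of 41 lists, 16 up and 8 down, at an adjusted p under 0.05, and 12 to 24 lists in the other 9 splits of the 6 libraries into 3 and 3. With an estimated correlation it called 0 (lowest adjusted p 0.373), and fry, which asks whether the genes of a list move one way on balance, called 0 (lowest adjusted p 0.325). Of 953 distinct genes tested in the lists, 0 passed over all genes. Adjusted over the list alone, 29 memberships passed, where a gene in more than 1 list counts in each. Of 16 cardiomyocyte markers 14 stand in another list, and of 26 glucocorticoid-responsive genes 11. The 24 calls are therefore not separate results. The values of members named here have an adjusted p of 0.427 or more over all genes, so none of them passed. Medians in sets 1 and 2 are given after the pooled median. In set 1 the only ET library is ET replicate 1, and in set 2 the only CONT library is CONT replicate 3. These are the libraries of the highest atrial markers, so a set median also carries the makeup of 1 library. Some named members share exon bases with a gene on the opposite strand, so their values are uncertain: Gabarapl1 (28.3%), Ctsl (26.8%), Txnip (19.4%), Ckm (15.5%) and Psmb8 (14.7%). In mean log2 CPM, as a difference from the mean of the 6 libraries, ET replicate 3 was the highest library in the PPAR-alpha (0.75), FoxO (0.65), glucocorticoid (0.62), ethanol metabolism (0.57), immediate early (0.42), NRF2 (0.34) and autophagy (0.21) lists and the lowest in the interferon (-1.05), skeletal muscle (-1.01), cell cycle (-0.84) and fibroblast (-0.46) lists. It was also the highest in the neutrophil (2.12) and hepatocyte (2.64) marker lists. ET replicate 1 was the highest in the stress response (0.30), inflammatory (0.47), skeletal muscle (0.68), fibroblast (1.17), matrix (1.19), mesothelial (3.07), atrial (3.28) and macrophage lists. With CONT replicate 3 and ET replicate 1 left out together, where group and set coincide, 12 of the 24 calls held. Those of the matrix, fibroblast, macrophage, inflammatory, immediate early, atrial, hepatocyte, heat shock, glycolysis and cardiomyocyte lists were lost, the sarcomere list was called up (0.25, adjusted p 0.0283), and the neutrophil list had too few genes for the test.

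Camera called up the lists of glucocorticoid-responsive genes and FoxO targets. Of 26 glucocorticoid-responsive genes, 24 were higher in ET, 10 without overlap, with a median of 0.73 (0.71 and 0.43 in the sets) and 7 members passing adjusted over the list alone. Cdkn1a, an inhibitor of cyclin-dependent kinases, was at 42.9 ± 11.2 CPM in ET against 16.3 ± 4.92 (log2 fold change 1.40 ± 0.28). Mt2, a metallothionein, was at 78.6 ± 15.6 against 23.0 ± 12.2 (1.78 ± 0.37), with 73.5% of its exon bases shared with an antisense gene, so its value is uncertain. Of the 26 genes 11, Cdkn1a and Mt2 among them, also stand in another list. The list's adjusted p was 1.69e-14 by camera and 0.373 with an estimated correlation. Of 29 tested FoxO targets and muscle atrophy genes, 28 were higher, with a median of 0.47 (0.35 and 0.30) and 2 passing adjusted over the list alone. Gabarapl1, which builds autophagosomes, had 0.89 ± 0.19 and Txnip, a thioredoxin inhibitor that limits glucose uptake, had 1.11 ± 0.25 (774 ± 197 CPM against 360 ± 42.6). The adjusted p of this list was 5.40e-12 and, with an estimated correlation, 0.677.

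The ethanol metabolism, stress response, autophagy and NRF2 lists were also called up. Of 22 tested genes for ethanol, aldehyde and acetate metabolism, 19 were higher in ET, with a median of 0.43 (0.12 and 0.22), 1 passing adjusted over the list alone, 0.20 without ET replicate 3 and 0.24 with the set term. Besides Aldh1a1, Adh1, the class I alcohol dehydrogenase, was at 49.2 ± 27.5 CPM against 17.9 ± 7.47 (1.46 ± 0.45), and the list's adjusted p was 1.76e-04 (adjusted p = 0.677 with an estimated correlation). Of 40 unfolded protein and integrated stress response genes, 39 were higher, with a median of 0.27 (0.35 and 0.20), 0 passing adjusted over the list alone. Mthfd2, an enzyme of mitochondrial one-carbon metabolism, had 1.38 ± 0.27 and Dnajc3, an endoplasmic reticulum cochaperone, 0.59 ± 0.15, while the 1 lower member was Ddit3, the stress-induced factor CHOP, at -0.60 ± 0.16. Camera gave an adjusted p of 9.57e-07 (adjusted p = 0.677 with an estimated correlation). Of 46 autophagy and lysosome genes, 39 were higher, with a median of 0.18 (0.08 and 0.10) and 0 passing adjusted over the list alone. The lysosomal protease gene Ctsl was at 163 ± 10.9 CPM against 112 ± 5.31 (0.54 ± 0.14) and Gabarapl1 at 122 ± 21.3 against 65.8 ± 9.86, and the list had an adjusted p of 5.87e-04 (adjusted p = 0.677 with an estimated correlation). Of 38 oxidative stress and NRF2 genes, 24 were higher, with a median of 0.14 (-0.08 and 0.19) and 3 passing adjusted over the list alone. Osgin1, an NRF2 target, had 1.15 ± 0.22, Mt2 is named with the glucocorticoid list, and the adjusted p was 0.00169 (adjusted p = 0.677 with an estimated correlation). This last call was lost without ET replicate 3, where the median was -0.01, and the median was 0.26 without CONT replicate 2 and 0.08 with the set term.

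The calls of the fatty acid oxidation and immediate early lists depended on single libraries. Of 36 PPAR-alpha targets, 27 were higher, with a median of 0.21 but -0.73 in set 1 against 0.37 in set 2, and 2 passed adjusted over the list alone. Angptl4 led the list, and Cpt1a, the carnitine palmitoyltransferase that limits fatty acid entry into mitochondria, was at 56.0 ± 1.56 CPM against 36.2 ± 2.78 (0.63 ± 0.12). The list had an adjusted p of 0.00299 (adjusted p = 0.757 with an estimated correlation), and was no longer called without ET replicate 2 (median 0.13), without ET replicate 3 (-0.13) or with the set term (-0.18). Its median was 0.09 without CONT replicate 1 and 0.55 without ET replicate 1, the library where its mean log2 CPM was lowest (-0.65 from the mean of the 6), while it was highest in ET replicate 3 (0.75). Of 26 immediate early genes, 14 were higher, with a median of 0.02 (0.02 and 0.35) and 1 passing adjusted over the list alone. Maff (0.97 ± 0.17) and Fosl2 (0.98 ± 0.24), both basic leucine zipper factors, led them, and the adjusted p was 0.0297 (adjusted p = 0.677 with an estimated correlation). That call was lost without CONT replicate 2 (median 0.08), CONT replicate 3 (-0.12), ET replicate 1 (0.05) or ET replicate 3 (-0.03), and the median was 0.26 without CONT replicate 1 and 0.17 without ET replicate 2.

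Camera called down the nuclear-encoded respiratory chain and glycolysis lists. Of 52 nuclear-encoded oxidative phosphorylation genes, 50 were lower in ET, 32 of them without overlap, with a median of -0.38 (-0.73 in set 1 and -0.06 in set 2) and 0 passing adjusted over the list alone. Cox7a1, the muscle form of a cytochrome oxidase subunit, was at 327 ± 28.9 CPM against 544 ± 141 (-0.73 ± 0.24), and Ndufs4, a subunit of complex I, was at 110 ± 11.7 against 153 ± 19.5 (-0.48 ± 0.17). The list's adjusted p was 1.29e-12 by camera and 0.677 with an estimated correlation. Of 31 glucose uptake and glycolysis genes, 21 were lower, with a median of -0.18 (-0.52 and -0.13) and 1 passing adjusted over the list alone. Eno3, the muscle enolase, was at 432 ± 71.6 CPM against 888 ± 42.6 (-1.04 ± 0.20) and Pgam2, the muscle phosphoglycerate mutase, had -0.57 ± 0.21. The adjusted p was 0.0239 (adjusted p = 0.698 with an estimated correlation), and the call was lost without CONT replicate 3 (median -0.09) or ET replicate 1 (0.02). The glycolysis median was -0.27 without CONT replicate 1, -0.11 without CONT replicate 2, -0.28 without ET replicate 2 and -0.32 with the set term. In mean log2 CPM both lists were lowest in ET replicate 1 (-0.45 and -0.44 from the mean of the 6 libraries), where the fibroblast (1.17) and atrial (3.28) lists were highest.

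Of 28 sarcomere genes, 18 were lower, with a median of -0.11 and a mean of -0.01, medians of -0.56 and -0.12 in the sets, and 1 passing adjusted over the list alone. Myh7b, a slow-tonic myosin heavy chain, was at 27.9 ± 12.9 CPM against 100.1 ± 24.3 (-1.84 ± 0.36) and Tnnc1, cardiac troponin C, had -0.66 ± 0.20. Camera called the list down (adjusted p 0.0437, and adjusted p = 0.757 with an estimated correlation), and not without CONT replicate 3 (median 0.01) or ET replicate 1 (0.09). The sarcomere median was -0.17 without CONT replicate 1, -0.18 without ET replicate 2, -0.26 without ET replicate 3 and -0.31 with the set term. Of 25 heat shock chaperones, 17 were lower, with a median of -0.13 (-0.24 and -0.19) and 0 passing adjusted over the list alone. The small heat shock protein gene Hspb6 (-0.64 ± 0.25) and the Hsp90 cochaperone gene Fkbp4 (-0.45 ± 0.19) had the lowest p, and the adjusted p of 0.0438 (adjusted p = 0.677 with an estimated correlation) was lost with RLE factors (-0.11) and without CONT replicate 2 (median -0.17), CONT replicate 3 (-0.02), ET replicate 1 (-0.12) or ET replicate 2 (-0.11). The heat shock median was -0.19 without CONT replicate 1 -0.23 without ET replicate 3 and -0.20 with the set term. The sarcomere and heat shock lists, too, were lowest in ET replicate 1 (-0.38 and -0.20 from the mean of the 6 libraries).

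Camera called down the interferon and cell cycle lists and called up the inflammatory list. Of 41 interferon-response genes, 37 were lower in ET, with a median of -0.43 (-0.39 and -0.07) and 0 passing adjusted over the list alone. Psmb9 and Psmb8, subunits of the immunoproteasome, had -1.13 ± 0.36 and -0.89 ± 0.33, and the adjusted p was 4.27e-06 (adjusted p = 0.677 with an estimated correlation). The median was -0.17 without CONT replicate 2, -0.66 without ET replicate 1, -0.22 with the set term, and -0.14, no longer called, without ET replicate 3. Of 36 cell cycle genes, 27 were lower, with a median of -0.55 (-0.22 and -0.15), -0.31 without ET replicate 3, -0.27 with the set term, -0.19 over the 23 genes that the stricter filter left, and 0 passing adjusted over the list alone. The mitotic kinesin gene Kif11 had -1.21 ± 0.40 at 0.467 ± 0.0616 CPM against 1.09 ± 0.398, and Mki67, a marker of dividing cells, had -1.25 ± 0.47 at 2.48 ± 1.02 against 5.93 ± 2.91. This list had an adjusted p of 1.78e-05 (adjusted p = 0.677 with an estimated correlation). Of 35 tested inflammatory genes, 23 were higher, with a median of 0.28 (0.35 and 0.14) and 0 passing adjusted over the list alone. Those with the lowest p were lower in ET: Nos2, the inducible nitric oxide synthase (-1.40 ± 0.35), and Cxcl9, a chemokine induced by interferon gamma (-1.995 ± 0.50). Camera's adjusted p was 0.0473 (adjusted p = 0.677 with an estimated correlation), and the call was lost with RLE factors, with library totals only, with a stricter filter, and without CONT replicate 2 (median 0.18), CONT replicate 3 (0.13), ET replicate 1 (0.12) or ET replicate 3 (0.09), and the median was 0.48 without CONT replicate 1.

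**Figure D2:**
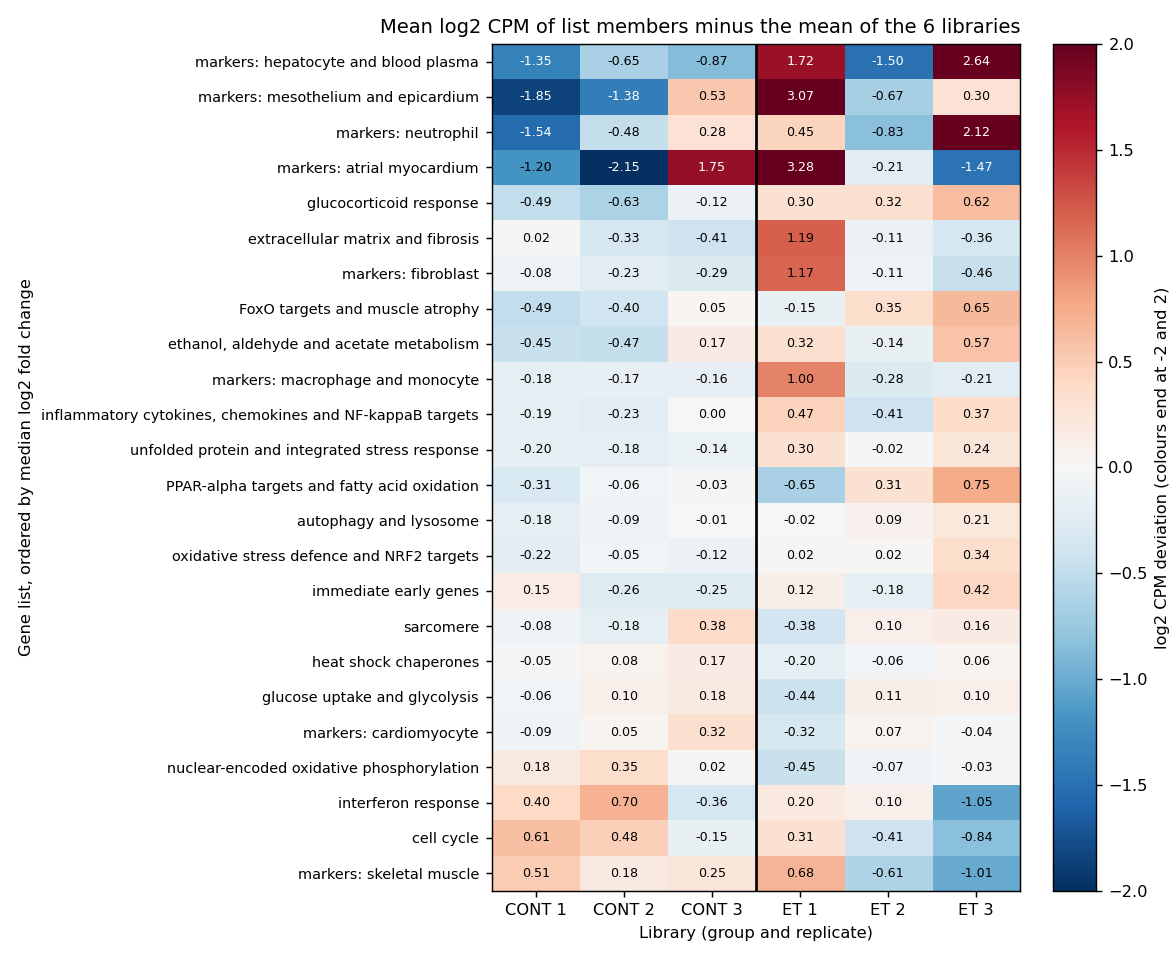
Mean log2 CPM of the tested members of the 24 called lists in each library, as a difference from the mean of the 6 libraries; red is higher and blue lower, colours end at -2 and 2, and the vertical line parts CONT from ET. The fibroblast list stands at 1.17 in ET replicate 1 and between -0.46 and -0.08 in the other 5 libraries, and the glucocorticoid list is below 0 in each CONT library and above 0 in each ET library.

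Matrix genes and markers of fibroblasts were highest in ET replicate 1. Of 44 extracellular matrix genes, 36 were higher in ET, with a median of 0.60 (1.27 in set 1 and 0.13 in set 2) and 2 passing adjusted over the list alone. Thbs1, a matricellular protein, was at 24.4 ± 16.2 CPM against 3.14 ± 0.976 (2.95 ± 0.52) and Lox, which crosslinks collagen, was at 21.1 ± 10.1 against 4.51 ± 1.55 (2.23 ± 0.40), both higher in all 3 ET libraries. The list had an adjusted p of 6.42e-07 (adjusted p = 0.677 with an estimated correlation), and 38 of its 44 members had their highest CPM in ET replicate 1. Without that library the median was -0.06 and the list was not called. Fibroblast markers had the same form: 12 of 14 were higher, with a median of 0.58 (1.52 and -0.01 in the sets), 2 passed adjusted over the list alone, and 13 were highest in ET replicate 1. Pdgfra was at 52.8 ± 17.4 CPM against 23.5 ± 0.257 (1.17 ± 0.24) and Dpep1 at 119.6 ± 33.4 against 47.6 ± 11.8 (1.33 ± 0.27), and the adjusted p was 4.85e-04 (adjusted p = 0.677 with an estimated correlation). The fibroblast median was 0.01, and not called, without ET replicate 1, and 0.92 without ET replicate 3. Of 18 macrophage and monocyte markers, 17 were higher, with a median of 0.35 (1.05 and -0.03) and 0 passing adjusted over the list alone. The scavenger receptor gene Cd163 had 1.29 ± 0.36 and the hyaluronan receptor gene Lyve1 1.499 ± 0.46, and the adjusted p was 0.00271 (adjusted p = 0.698 with an estimated correlation). The macrophage median was -0.11 without ET replicate 1, where the call was lost, 0.60 without ET replicate 2 and 0.59 without ET replicate 3.

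Atrial, mesothelial and epicardial markers were uneven between libraries. Of 11 tested atrial markers, 11 were higher in ET on average and 10 had their highest value in ET replicate 1, with a median of 1.28 (4.65 and -1.34 in the sets) and 0 passing adjusted over the list alone. Myl7, the atrial regulatory myosin light chain, stood at 1527 CPM in ET replicate 1 and 340.5 in CONT replicate 3, against 17.0, 0.487, 34.4 and 2.54 in CONT replicates 1 and 2 and ET replicates 2 and 3. The members of lowest p were Tbx5 (0.82 ± 0.46) and Upk1b (3.03 ± 1.73), and the adjusted p was 0.0311 (adjusted p = 0.698 with an estimated correlation). The atrial call was lost without CONT replicate 1 (median 0.99), CONT replicate 2 (1.01) or ET replicate 1 (-0.81), and with library totals only (1.49), the stricter filter (1.18) or the set term (1.05), and the median was 4.62 without CONT replicate 3. Of 11 mesothelial and epicardial markers, 10 were higher, with a median of 2.32 (3.66 and -0.74) and 0 passing adjusted over the list alone, among them the keratin genes Krt18 (3.84 ± 1.06) and Krt8 (3.86 ± 1.23). Krt18 was at 11.5 CPM in ET replicate 1 and 12.4 in ET replicate 3, and Krt8 at 12.2 and 10.4, against 1.09 or less in the other libraries. Of the 11 mesothelial markers, 10 were highest in ET replicate 1. Upk3b and Msln were at 67.2 and 44.7 CPM there, but at 2.28 and 1.07 in ET replicate 3. The mesothelial list had an adjusted p of 4.34e-05 (adjusted p = 0.677 with an estimated correlation), and its median was -0.20, not called, without ET replicate 1 and 4.13 without CONT replicate 3.

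Of 7 tested hepatocyte and plasma protein genes, 7 were higher in ET, with a median of 3.26 (1.08 and 2.04) and 1 passing adjusted over the list alone. In mean log2 CPM the list was high in ET replicates 1 and 3 (1.72 and 2.64 from the mean of the 6 libraries). Alb, serum albumin, was at 46.8 CPM in ET replicate 3 and from 0.0274 to 2.16 in the other libraries, and Ttr, transthyretin, at 1.55 ± 1.63 CPM against 0.147 ± 0.0515 (3.38 ± 0.89). The adjusted p was 4.85e-04 (adjusted p = 0.677 with an estimated correlation), the median was 1.18 without ET replicate 3, and the call was lost without ET replicate 1 (2.91). Of 5 tested neutrophil markers, 5 were higher, with a median of 1.41 (1.17 and 0.50) and 0 passing adjusted over the list alone. Mmp9 had 1.41 ± 0.47, and S100a8 was at 17.5 CPM in ET replicate 3 against 2.53 or less elsewhere (2.71 ± 1.22). The adjusted p was 0.0120 (adjusted p = 0.677 with an estimated correlation), and the median was 0.04, not called, without ET replicate 3, 2.31 without CONT replicate 2, 3.01 without CONT replicate 3 and 2.699 without ET replicate 2.

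**Figure D3:**
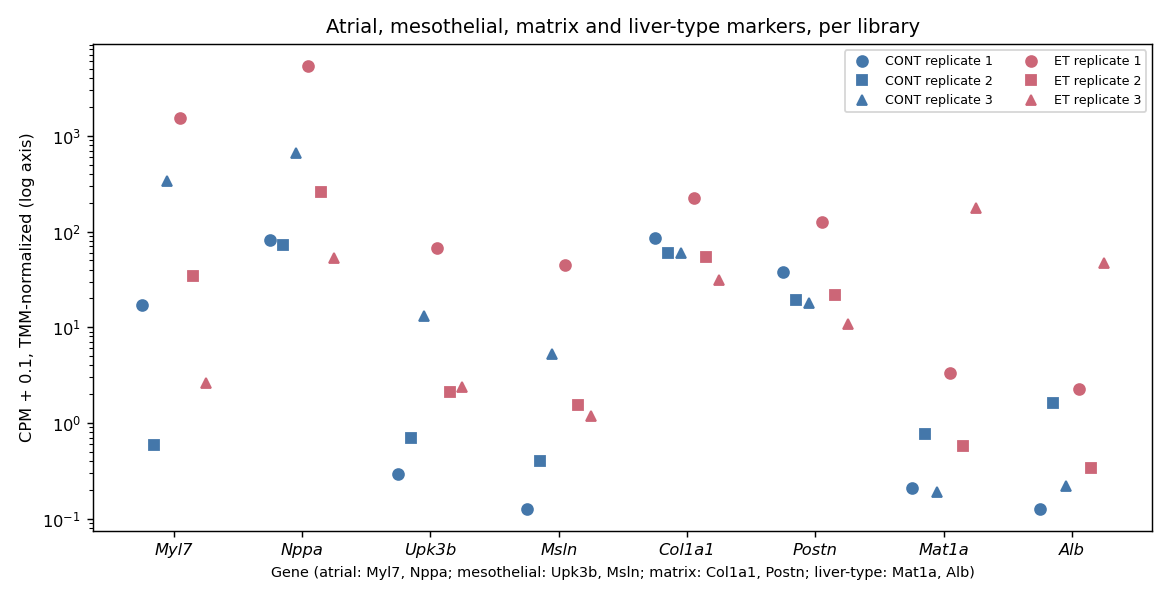
TMM-normalized CPM plus 0.1 (log axis) of single markers of atrium (Myl7, Nppa), mesothelium (Upk3b, Msln), matrix (Col1a1, Postn) and liver (Mat1a, Alb) in each library; colour gives the group and marker shape the replicate. ET replicate 1 is the highest in the first 6 genes, with Myl7 at 1527 CPM, and ET replicate 3 in the last 2, with Mat1a at 178, while 61.5% of the exon bases of Nppa are shared with an antisense gene, so its values are uncertain.

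Camera called down the skeletal muscle and cardiomyocyte marker lists. Of 6 tested skeletal muscle markers, 4 were lower, with a median of -0.88 (-0.29 and -0.53) and 0 passing adjusted over the list alone. Casq1, the skeletal calsequestrin, had -1.30 ± 0.43 and Mylpf, a fast light chain, -1.23 ± 0.45, at an adjusted p of 0.0161 (adjusted p = 0.677 with an estimated correlation). That call was lost without CONT replicate 3 (median -0.77), ET replicate 2 (-0.16) or ET replicate 3 (0.06), and the median was -0.43 without CONT replicate 1 and -0.35 without CONT replicate 2. Of 16 cardiomyocyte markers, 12 were lower, with a median of -0.24 (-0.76 and -0.17) and 0 passing adjusted over the list alone. Tnni3, cardiac troponin I, was at 2972 ± 110.2 CPM against 4501 ± 565 (-0.60 ± 0.19), and Ckm, the muscle creatine kinase, had -0.71 ± 0.28. The list had an adjusted p of 0.0123 (adjusted p = 0.677 with an estimated correlation). It was not called without CONT replicate 3 (median -0.20) or ET replicate 1 (-0.14), and the median was -0.39 without ET replicate 3 and -0.39 with the set term. This list was lowest in ET replicate 1 (-0.32 in mean log2 CPM from the mean of the 6 libraries).

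The other 17 tested lists were not called. Among heart cell types, endothelial markers had a median of -0.15 (10 of 15 lower), mural cell markers 0.16 (11 of 14 higher), erythroid markers 0.19 (8 of 9 higher), Schwann and neuronal markers -0.34 (7 of 11 lower) and adipocyte markers 0.52 (7 of 10 higher, with the test pointing down). Of the lymphocyte markers only 4 had enough counts, too few for the test, with a median of -0.41. Mitochondrially encoded respiratory chain genes had a median of -0.14 (11 of 13 lower), the tricarboxylic acid cycle -0.08 (15 of 21 lower), branched-chain amino acid catabolism 0.11 (17 of 24 higher) and fatty acid and triglyceride synthesis 0.19 (17 of 29 higher). The cardiac stress and fetal programme had 0.18 (11 of 19 higher), apoptosis and p53 targets 0.09 (20 of 33 higher), calcium handling 0.01 with a test pointing down (16 of 28 higher) and ion channels 0.01 with a test pointing down (15 of 28 higher). Calcium handling turned to -0.01 under the stricter filter. Medians also turned sign without single libraries: adipocyte markers were at -1.08 without ET replicate 1 and 1.15 without CONT replicate 3, and the tricarboxylic acid cycle at 0.24 without ET replicate 1. Without ET replicate 3 the cardiac stress programme was at -0.13, branched-chain amino acids at -0.14 and ion channels at -0.12, and calcium handling was at -0.10 without ET replicate 2. Endothelial markers were at 0.05 and hypoxia at 0.11 without CONT replicate 1, clock genes at -0.19 without CONT replicate 2, apoptosis and p53 targets at -0.01 and cholesterol synthesis at 0.05 without CONT replicate 3, and ribosomal proteins at 0.03 without ET replicate 2. Lymphocyte markers had enough genes for the test in fits without libraries, and were called down without ET replicate 1 (-1.04) and without ET replicate 2 (-0.34). Adjusted over the list alone, 2 members passed in the apoptosis and p53 list, 2 in cholesterol synthesis, 1 in ion channels and 1 in the Schwann and neuronal list, and 0 in the other 13. Clock genes had 0.03 with a test pointing down (11 of 21 higher). Scaling by library totals only, which moved the median of all genes by 0.11, turned the sign of 3 medians: cytosolic ribosomal proteins (-0.05, and 0.07 with totals), cholesterol synthesis (-0.03 with a test pointing up, and 0.10) and hypoxia (-0.01 with a test pointing up, and 0.10).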

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

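The fits with a set term, those without CONT replicate 3 and ET replicate 1, and DESeq2 without single libraries were chosen only after the result was seen. Called by edgeR were 0 genes under each scaling, filter and removal of genes, against a fold of 1.2, at a threshold of 0.10, without each library and with the set term, with 565 to 2610 genes at an unadjusted p under 0.05 in the fits without 1 library, and 0 by limma-voom and log2(TPM + 1). DESeq2 called 184 genes (105 higher, 79 lower), and 21, 38 and 437 without CONT replicates 1, 2 and 3 and 405, 212 and 197 without ET replicates 1, 2 and 3. With the set term DESeq2 called 198 (120 higher, 78 lower), 130 of them among the 184. In simulated data with no change DESeq2 called 28, which bears on its calls. Limma-trend on log2(TPM + 0.1) called 2 genes, 2 lower, and the cause was not tested. Without CONT replicate 3 and ET replicate 1 edgeR called 828 (529 higher, 299 lower), where group and library set coincide by construction. The 10 named genes passed in 3 of 22 alternatives. Their groups do not overlap, which largely fixes the sign of the change, so that a sign kept under other fits shows no stability.

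Lists called were 0 with an estimated correlation and 0 by fry, where the tests change and the medians stay as they were: glucocorticoid 0.73, FoxO 0.47, ethanol metabolism 0.43, stress response 0.27, PPAR-alpha 0.21, autophagy 0.18, NRF2 0.14, immediate early 0.017, matrix 0.60, inflammatory 0.28, interferon -0.43, cell cycle -0.55, oxidative phosphorylation -0.38, glycolysis -0.18, heat shock -0.13, sarcomere -0.11, fibroblast 0.58, macrophage 0.35, neutrophil 1.41, atrial 1.28, mesothelium 2.32, hepatocyte 3.26, skeletal muscle -0.88 and cardiomyocyte -0.24. Lists called numbered 22 with RLE factors, 23 with library totals, 19 of 38 tested with the stricter filter and 24 with the set term. Losing their call were inflammatory (0.30) and heat shock (-0.11) with RLE, inflammatory (0.32) and atrial (1.49) with totals, inflammatory (0.30) and atrial (1.18) with the filter, and PPAR-alpha (-0.18) and atrial (1.05) with the set term. The neutrophil, hepatocyte and skeletal muscle lists had fewer than 5 genes left under the stricter filter and no test there. Called lists whose median moved by over 1.5 times were autophagy (0.26), NRF2 (0.24), macrophage (0.54), interferon (-0.27), glycolysis (-0.097), heat shock (-0.052), sarcomere (-0.034) and immediate early (0.12) with totals. With the set term these were ethanol metabolism (0.24), NRF2 (0.082), immediate early (0.14), interferon (-0.22), cell cycle (-0.27), glycolysis (-0.32), heat shock (-0.20), sarcomere (-0.31) and cardiomyocyte (-0.39). Cell cycle (-0.19) and immediate early (0.0098) moved so with the filter, and immediate early (0.034) with RLE. Gaining a call were Schwann (-0.16) with totals, and the tricarboxylic acid cycle (-0.40) and ion channels (-0.22) with the set term. The cause was not tested.

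Without CONT replicate 3 and ET replicate 1, 21 lists were called, 12 of the 24 in the same direction and the sarcomere list in the other. The neutrophil list had fewer than 5 genes there and no test, and the lymphocyte list, tested there, was called (-1.40). There the test turned for matrix (-0.18), inflammatory (0.15), heat shock (-0.028), tricarboxylic acid cycle (0.28), glycolysis (0.022), ion channels (0.44), sarcomere (0.25), fibroblast (-0.018), macrophage (-0.14) and cardiomyocyte (0.0031). Calls were lost for immediate early (-0.11), atrial (0.76) and hepatocyte (2.55) and gained for fatty acid synthesis (0.27), branched-chain amino acids (0.39), ribosomal (-0.18), endothelial (-0.47) and Schwann (-0.84). Medians of FoxO (0.72), PPAR-alpha (0.56), cell cycle (-0.97) and interferon (-0.85) moved by over 1.5 times with their calls kept. Group and set coincide there, and 1 fewer library per group was used.

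Without single libraries 7 of the 24 lists kept their call in all 6 fits. The medians of lists that lost, gained or turned a call ranged as follows: PPAR-alpha -0.13 to 0.55, matrix -0.057 to 0.89, sarcomere -0.26 to 0.093, fibroblast 0.0076 to 0.92, macrophage -0.11 to 0.60 and atrial -0.81 to 4.62, each of these turning in test direction. Others were glycolysis -0.28 to 0.024, heat shock -0.23 to -0.016, immediate early -0.12 to 0.26, inflammatory 0.095 to 0.48, interferon -0.66 to -0.14, NRF2 -0.011 to 0.26, cardiomyocyte -0.39 to -0.14, hepatocyte 1.18 to 3.83, mesothelium -0.20 to 4.13, neutrophil 0.041 to 3.01 and skeletal muscle -1.13 to 0.055. Gaining a call in at least 1 fit were apoptosis and p53 (-0.0089 to 0.14), branched-chain amino acids (-0.14 to 0.33), ion channels (-0.12 to 0.18), ribosomal (-0.13 to 0.026), fatty acid synthesis (0.054 to 0.33), Schwann (-0.98 to -0.0094), endothelial (-0.32 to 0.052), erythroid (0.074 to 0.99), mural (0.056 to 0.35), mitochondrially encoded (-0.31 to -0.016) and tricarboxylic acid cycle (-0.36 to 0.24). The cause was not tested beyond the smaller number of libraries. The libraries held 28838386 to 37762233 counts, and edgeR called 16 of 100 simulated 2-fold changes, so that smaller changes were rarely detectable.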

Other observations

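All tests of explanations named here were chosen only after the result was seen, except the second atrial list and the splits of the samples for gene lists. The following single genes were chosen after their values were seen, were called by DESeq2 but not by edgeR, and stand for no group. Aplnr, the apelin receptor, was at 8.51 ± 3.86 CPM in ET against 34.5 ± 19.5 (SD, n = 3; log2 fold change -2.02 ± 0.52), and its ligand gene Apln had -1.63 ± 0.45. Dll4, a Notch ligand, was at 13.1 ± 1.16 against 30.2 ± 8.74 (-1.20 ± 0.23), and Plxnd1, a semaphorin receptor, had -1.11 ± 0.29. H2-Aa, an MHC class II chain, was at 9.03 ± 2.08 against 20.6 ± 6.79 (-1.19 ± 0.28).

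Higher in all 3 ET libraries were Thbs2, a matricellular protein (42.4 ± 16.2 against 14.8 ± 0.530, 1.51 ± 0.27), Hmox1, the inducible heme oxygenase (20.5 ± 8.19 against 7.74 ± 0.165, 1.41 ± 0.31), and Pdk4, the starvation-induced inhibitor of pyruvate dehydrogenase (1124 ± 724 against 213 ± 62.0, 2.40 ± 0.62), called by DESeq2. Pdk4 was at 289 CPM in ET replicate 1, close to 271 in CONT replicate 3, and at 1564 and 1520 in ET replicates 2 and 3. Gm45774, antisense to Mt2, had the lowest p of all genes (2.73e-05, 2.19 ± 0.23) and was kept out of the named genes by its name. At a mean of 3.26 CPM it shares 16.2% of its exon bases with Mt2, which was at 50.8 CPM, so its value is uncertain.

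The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 0 edgeR calls and the highest other 1, and with 0 calls each of the 10 splits necessarily gives as many, so nothing is read from it. DESeq2 called 184 genes in the real split and 1401 in the highest other, and 2 splits gave as many, the real one included. For gene lists the real split gave 24 and the highest other 24, again 2 splits with the real one included, and the other 9 splits gave from 12 to 24. The split with 1401 DESeq2 calls was that of the library sets, which points to a structure of the samples, and the edgeR fit with the set term called 0 genes with 1579 at an unadjusted p under 0.05.

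The sets, CONT replicates 1 and 2 with ET replicate 1 against CONT replicate 3 with ET replicates 2 and 3, also separated a second Nnt gene model, counted at 0 in the first set and at 1937, 3141 and 1726 in the second. Trends with transcript length (Spearman coefficient across genes, CONT replicate 3 minus ET replicate 1, -0.0417) and with GC share (ET replicate 1 minus CONT replicate 3, -0.0233) were of the other sign than these sets need. Each difference sets 1 library against 1. Libraries within a set differed more, with length coefficients of -0.19, -0.35 and 0.11 in the first and 0.07, 0.29 and 0.04 in the second. Neither bias can be decided on from these values. The GC coefficients did not overlap between the groups. They were 0.23, 0.17 and -0.035 in CONT replicates 1 to 3 and -0.058, -0.18 and -0.10 in ET replicates 1 to 3. A GC trend thus runs along with the comparison of ET with CONT, and its part in the gene and list results was not tested. Swapped labels of CONT replicate 3 and ET replicate 1 stay open: the split by labels left 2398 genes without overlap, against 1518 in the highest of the 8 splits that are neither this nor the sets, too few splits to decide. No batch is given in the labels.

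Atrial, mesothelial and fibroblast markers were high in ET replicate 1, which had 59 genes at least 5 times above every other library. Fibroblast and endothelial markers, the only ones compared in ET replicate 1, argue against fewer cardiomyocytes with every other cell type up alike. Fibroblast markers there exceeded endothelial ones by 1.28 (fibroblast quartiles 1.09 and 1.81, endothelial -0.15 and 0.41). A lower share of cardiomyocytes as such is not excluded by this comparison. Cardiomyocyte markers had a median log2 ratio of -0.77 in ET replicate 1 over the median of the 5 other libraries. A shift shared by the ET libraries stays open: the 36 markers had a median log2 fold change of -0.24 without that library (quartiles -0.80 and 0.24), but 35 of them had 0.53 with CONT replicate 3 left out too (quartiles -0.040 and 1.07), where mesothelial markers were still called (1.61), atrial ones were not (0.76), fibroblast ones were at -0.018, and group and library set coincide. The bounds of both tests were rewritten after first versions had been seen, so neither test alone decides on its explanation. A candidate explanation is atrial tissue in the sample: a second atrial list, 12 genes tested and none in another list, had a median of 1.21 over the other libraries, but 8 of 12 members were highest in ET replicate 1, fewer than the prediction asked, so it stays open. With ET replicate 1 set aside, 9 of the 12 were highest in CONT replicate 3, which also had Myl7 at 340.5 CPM. Of the first atrial list 5 of 12 genes stand in another list, and 10 of 11 tested atrial, 8 of 11 mesothelial, 14 of 14 fibroblast and 12 of 12 second-list genes had a CPM of at least 1 in CONT, with Myl7 at 1527 CPM in ET replicate 1. Nppa was at 5352 there and 656 in CONT replicate 3, and 61.5% of its exon bases are shared with an antisense gene, so its values are uncertain.

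ET replicate 3 had 53 genes at least 5 times above every other library, among them Mat1a (178 CPM), Bhmt (108) and Alb (46.8). The median of 8 plasma protein genes was 6.74 CPM there. Of the hepatocyte and plasma list 1 of 12 genes stands in another list, and 3 of 7 tested had a CPM of at least 1 in CONT. Without ET replicate 3 that list had a median of 1.18 and was still called. No explanation of these values, technical or biological, is weighed here.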
